A study of Mus musculus with 2 samples.

How the data were processed

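RNA was measured in nuclei of flash-frozen hippocampus by 3' droplet sequencing (10x Genomics, v3.1 chemistry), with 28 and 91 bp reads, per the labels' protocols. About 20 mg of tissue was used per library for a target of 10000 nuclei. The groups were 5XFAD and 5XFAD with MR1 knockout, at 8 months of age, with 1 library each, and each library pooled 2 mice, 1 of each sex. The deposited files hold raw counts, that is, whole UMI counts per gene and barcode for the barcodes kept by the authors' cell caller. Per the file headers the authors used Cell Ranger 7.0.0, and the submitters' processing notes name the mm10 build and Seurat, whose role is not given. The annotation release, the strand setting and whether introns were counted are not given in the sources used here. The gene list of the files pairs gene IDs with symbols; 32235 of its 32285 IDs matched GENCODE M21 (GRCm38, the build called mm10), which gave the coordinates. No cell annotation was used here, so cell classes were rebuilt and can differ from the study's.

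Nuclei were kept with at least 500 genes detected and under 5% mitochondrial UMIs, which left 15408 of 25238 barcodes in the 5XFAD library and 22263 of 26212 in the library labelled MR1 knockout. The mitochondrial limit alone removed 35.8% and 8.92% of the barcodes, which had median mitochondrial shares of 3.43% and 1.41%. Doublets were scored with Scrublet (in scanpy) within each library. The threshold was set to the expected doublet share at 0.8% per 1000 nuclei, because the automatic threshold marked 22.0% in the first library and 5.50% in the other. This marked 19.5% and 20.4% of the nuclei; nuclei with both Xist and Y-linked UMIs implied 18.0% and 16.4%. Mixed clusters (5 of 37, with 356 and 542 nuclei) were left out. These were led by markers of more than 1 class, as was the only endothelial cluster, or had both Xist and Y-linked UMIs in at least 15% of their nuclei. Clusters 20 and 34 (28.4% and 24.4% such nuclei) were led by microglial genes and held 267 and 360 nuclei. This left 12043 nuclei with 56506251 UMIs and 17170 nuclei with 56280626 UMIs. A mouse's nuclei were told apart by sex-linked RNA. Nuclei with at least 2 Xist UMIs and no Y-linked UMI went to the female mouse, and those with at least 1 UMI of Ddx3y, Eif2s3y, Kdm5d or Uty and no Xist to the male mouse. These were 5295 and 3450 nuclei in the 5XFAD library and 8993 and 3087 in the other, and the rest went to neither. Both mice of a label shared a capture, so the mice of a library are not independent replicates.

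Both libraries were clustered together without correction. The 2500 most variable genes were used without Xist, Tsix, Y-linked and mitochondrial genes, with 40 principal components, 20 neighbours and Leiden clustering at a resolution of 1.5. Classes were named from 21 sets of markers fixed in advance. A cluster was named if at least 3 markers of a class were among its top 50 genes, its leading genes did not go against the name, and it was not shallow without a marker among its top 10 genes. Shallow meant that its median of UMIs times 3 lay below the median of the library, in either library. Of the clusters, 18 took 13 names, and 14 stayed unnamed. The 9 classes with at least 200 nuclei in each library were compared. Raw UMIs were summed per library and class and scaled to CPM over the class. Ratios carry an exact conditional binomial 95% interval, shares an exact binomial (Clopper-Pearson) interval and CPM an exact Poisson interval, all for counting error only. There was no test between the groups, since nuclei of a library are not replicates.

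The doublet threshold was set after the automatic shares were seen. Leaving out clusters by their nuclei with both Xist and Y-linked UMIs was not fixed in advance either. The limits on genes detected and on mitochondrial UMIs were fixed before the data were examined. So were the gene lists, the markers and the rule for named genes. In each class the rule took genes with at least 100 UMIs over both libraries, outside the Y chromosome, Xist, Tsix and the mitochondrial genome, at 20% or more of their highest class CPM, and with the same direction in the female and in the male mice. They were ranked by the bound of the interval nearest to 1, and the 5 highest and 5 lowest were named (10 and 10 in microglia). Up to 6 genes with the same direction in all 9 classes, up to 4 members per list, and Mr1, Thy1 and App were also named. Some genes that these rules named are not reported here. A list's value was the median log2 ratio of its members with at least 20 UMIs in the class, with a prior count of 0.5. Its percentile is among 10000 random lists of the same size, matched on expression in 20 bins, and only describes these libraries. Of 28 lists, 2 were for endothelial cells alone and gave no value, since the endothelial cluster was mixed, as did MHC class I genes in endothelial cells. Clec7a and Ddit3, each a member of a list, were not analysed here.

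The calculation was tested on simulated data from each of 2 classes, with 200 changed genes. In microglia, among 2813 genes, the interval held the true ratio for 96.1% of the 102 genes changed 2-fold and 96.9% of the 98 genes changed 4-fold, and lay on the right side of 1 for 99.0% and 100%. In CA1 pyramidal neurons, among 9368 genes, the interval held the true ratio for 96.1% and 92.9%, and lay on the right side for 99.0% and 100%. For unchanged genes it held the true ratio in 95.9% and 95.3%. A list of 58 doubled genes had a median log2 ratio of 0.98 in microglia and 0.99 in CA1 pyramidal neurons. Of 100 unchanged lists, 6 and 4 fell outside the central 95% of random lists. These data were simulated with counting noise alone, so they say nothing of the spread between mice.

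Alternatives fixed in advance were at least 1000 or 200 genes per nucleus, under 1% mitochondrial UMIs, doublets kept, nuclei with Xist and Y-linked UMIs left out, nuclei of either sex alone, 0.5 or 2 times the clustering resolution, the class with the highest marker score, and shares among glial and vascular nuclei. For genes and lists, TMM scaling (edgeR's method, written out in numpy), thinning to 750 UMIs per nucleus, the mean CPM over nuclei, list minimums of 100 or 1 UMIs and a prior count of 5 were also tried. No mitochondrial limit, the automatic doublet threshold, the female 5XFAD mouse against the male mouse of the other library, each dentate granule cluster alone, removal of each gene's lowest class level and, for shares, mixed clusters kept under their leading class were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.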

Results

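Nuclei from the hippocampus of 8-month-old mice were profiled by droplet-based single-nucleus RNA sequencing. All mice carried 5XFAD, a set of transgenes that drives amyloid plaque formation through mutant human APP among others. A first library came from 5XFAD mice, and the other from 5XFAD mice labelled as MR1 knockouts. MR1 is the molecule that presents vitamin B metabolites to mucosal-associated invariant T (MAIT) cells, and the series title names the effect of this axis on dystrophic neurites, the swollen axons around plaques. Each library pooled 1 female and 1 male mouse. The 5XFAD library held 25238 barcodes with 106861726 UMIs (a median of 3135 per barcode), and the library labelled MR1 knockout held 26212 barcodes with 85678909 UMIs (a median of 2458). After filtering, 12043 nuclei with a median of 3710 UMIs and 17170 nuclei with a median of 2525 UMIs were kept. With 1 library per group there was no test, so the comparison describes these libraries, and all intervals are 95% intervals that cover counting error only. All ratios set the library labelled MR1 knockout over the 5XFAD library, in CPM, the UMIs of a gene scaled to the UMIs of the class.

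The first question was whether the targeted gene followed its label, and its RNA did not. Mr1 (ENSMUSG00000026471, chromosome 1, 155127277 to 155146814 in mm10) had 33 UMIs in the 5XFAD library and 62 in the library labelled MR1 knockout. These counts gave 0.584 CPM (exact Poisson interval 0.402 to 0.820) and 1.10 CPM (0.845 to 1.41), a ratio of 1.89 (1.22 to 2.97). The female mice had 14 and 27 UMIs, and the male mice had 12 and 11. In microglia, where 6 and 7 UMIs were counted, the ratio was 0.504 (0.145 to 1.82), so no difference was detectable at this depth. A 3' tag or an intron count can lie outside the deleted part of a knockout allele, so these counts check nothing about the protein. Since the gene's RNA went against its label, every direction in the comparison belongs to the library labelled MR1 knockout and not to a shown loss of MR1.

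Thy1 and App, which the disease model draws on, were compared in each class. The 5XFAD transgenes are driven by Thy1 sequences, and Thy1 and App were both higher over all nuclei. Thy1, a neuronal surface glycoprotein, had a ratio of 1.49 (1.47 to 1.51) over all nuclei, 2.19 (2.10 to 2.28) in dentate granule neurons and 1.47 (1.41 to 1.53) in CA1 pyramidal neurons. App, the precursor of amyloid beta, had a ratio of 1.11 (1.10 to 1.13) over all nuclei and 1.46 (1.40 to 1.52) in dentate granule neurons of clusters 0 and 2, with 1.70 in the female and 1.06 (0.942 to 1.18) in the male mice. App was lower in microglia (0.849, 0.738 to 0.979) and oligodendrocytes (0.931, 0.868 to 0.999), and in CA1 neurons it was at 1.23 in the female and 0.915 (0.851 to 0.985) in the male mice. Reads from the transgenes and from the mouse genes were not told apart here.

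Microglia made up a larger share of the library labelled MR1 knockout. They were 2.01% of the nuclei (242 of 12043, exact binomial interval 1.77 to 2.28) in the 5XFAD library and 4.47% (767 of 17170, 4.16 to 4.79) in the other, a ratio of 2.22 (1.92 to 2.58). The ratio was 1.72 in the female mice and 2.15 in the male mice. Clusters 20 and 34, led by microglial genes, were left out because at least 15% of their nuclei held RNA of both sexes. This limit was not fixed in advance. With the 267 and 360 nuclei of these clusters counted as microglia and the other mixed clusters kept, the ratio was 1.55 (1.39 to 1.72). Dentate granule neurons were 12.3% and 24.1% of the nuclei, a ratio of 1.96 (1.85 to 2.08), but the female mice had similar shares (ratio 1.05) and the male mice did not (6.64). Subicular or cortical excitatory neurons were 5.80% and 1.57%, a ratio of 0.270 (0.234 to 0.312). Oligodendrocyte precursors were 1.93% and 2.73% (ratio 1.42; 0.558 with the female 5XFAD mouse set against the male mouse of the other library), oligodendrocytes 6.68% and 5.41% (0.809; 7.78 under 1% mitochondrial UMIs, with an interval of 3.47 to 21.6), and astrocytes 1.98% and 1.49% (0.754; 2.35 under 1% mitochondrial UMIs). CA1 pyramidal neurons were 9.38% and 7.57% (0.807; 0.312 in the female and 1.68 in the male mice), CA2/CA3 pyramidal neurons 9.75% and 9.85% (1.01; 0.453 and 3.10), and inhibitory neurons 8.20% and 9.53% (1.16; 0.826 and 1.75). Choroid plexus epithelial cells, which make the cerebrospinal fluid, numbered 2 and 93. Committed oligodendrocyte precursors numbered 42 and 112, vascular leptomeningeal cells 34 and 97, and Cajal-Retzius cells 16 and 61. Clusters left without a name held 41.2% and 31.2% of the nuclei. The microglial ratio was below 1 when nuclei needed at least 1000 genes (0.746) or when the female 5XFAD mouse was set against the male mouse of the other library (0.784), and was 6.80 among nuclei under 1% mitochondrial UMIs. The mice of a library also differed in their unnamed clusters, which held 20.8% and 61.2% of the nuclei of the female and the male 5XFAD mouse, and 43.5% and 17.5% in the other library. The brain region of these clusters was not determined here. Ratios within the glial classes could therefore also compare tissue of different regions, which was not tested.

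**Figure D1:**
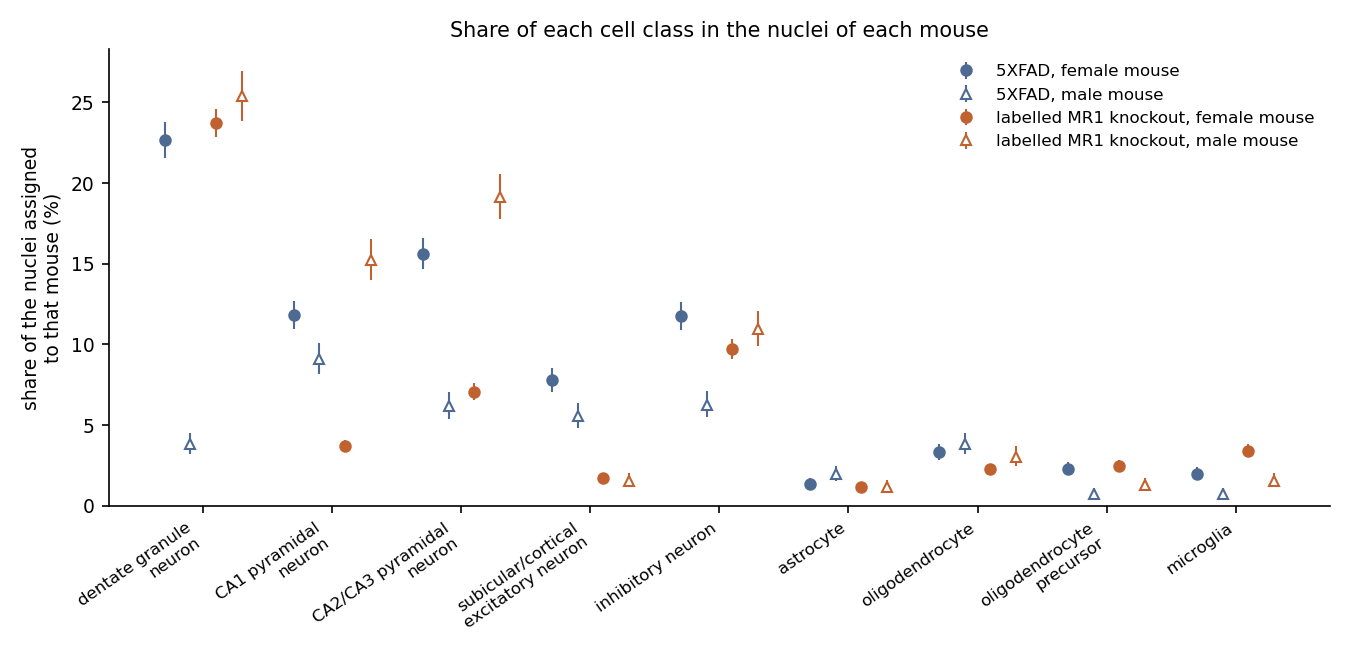
Share of each cell class among the nuclei assigned to each of the 4 mice, in percent; points are shares and bars are exact binomial 95% intervals, which cover counting error only. Dentate granule neurons were 12.3% and 24.1% of all nuclei in the 2 libraries, and the male 5XFAD mouse has the lowest share of them.

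In microglia, H2-K1, H2-D1 and Apoe had higher CPM in the library labelled MR1 knockout. All UMIs per microglial nucleus had means of 1522 in the 5XFAD library and 1112 in the other, a ratio of 0.731. Part of a higher CPM can thus come from fewer other UMIs, which weighs more on Apoe than on H2-K1 and H2-D1, whose ratios were larger. H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347) and H2-D1 (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499), the classical heavy chains of MHC class I, had ratios of 2.28 (1.67 to 3.17; 48 and 253 UMIs) and 2.08 (1.65 to 2.64; 90 and 433 UMIs). In the female and male mice the ratios were 2.16 and 1.54 for H2-K1, and 1.47 and 3.20 for H2-D1. Apoe, the lipid carrier that microglia raise around plaques, had a ratio of 1.53 (1.46 to 1.59; 2906 and 10268 UMIs). Of the 18 measured members of the MHC class I and peptide loading list, 15 were higher, with a median log2 ratio of 0.48 at the 99.9th percentile; the median was 0.53 in the female mice and -0.14 in the male mice. B2m, the light chain of MHC class I, had a ratio of 1.43 (1.2 to 1.72). All 6 measured MHC class II members were higher (median log2 ratio 0.73, percentile 98.3; 0.02 in the male mice), 1 of them with an interval above 1, the invariant chain Cd74 (1.71, 1.12 to 2.69).

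Disease-associated and homeostatic genes of microglia went both ways. Of 34 measured disease-associated microglia genes, 18 were higher and 16 lower, with a median log2 ratio of 0.08 (percentile 94.4; 0.78 under 1% mitochondrial UMIs and 0.32 with no mitochondrial limit); Spp1, the secreted phosphoprotein osteopontin, had a ratio of 1.89 (1.23 to 2.98) and the lysosomal protease Ctsd 1.35 (1.23 to 1.49). Of 23 measured homeostatic microglia genes, 11 were higher and 12 lower, with a median of -0.04 (percentile 44.8) that was 0.10 when nuclei were thinned to 750 UMIs. Among them Tmem119 was 2.77 (1.5 to 5.60), while the transcription factor Mef2c was 0.679 (0.612 to 0.753). Plaque-induced genes were higher for 40 of 46 members (median log2 ratio 0.24, percentile 100), and complement genes for 6 of 10 (0.11, percentile 86.5), with C1qa at 1.46 (1.32 to 1.62). The complement median was 0.11 in the female and -0.23 in the male mice. Interferon response genes were higher for 15 of 21 members (0.32, percentile 98.8), with a median of 0.00 in the male mice. Inflammatory cytokine and NF-kB genes were higher for 7 of 15 members (-0.01, percentile 40.3, and 0.01 under TMM scaling and under thinning). Their median was -0.04 in the female and -0.80 in the male mice. Rel, an NF-kB subunit, was at 0.479 (0.299 to 0.768).

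The fixed rule named further genes in microglia, some of them at background. Calb1, Gfap, U2af1 and Sh3bgrl3 had ratios of 2.57, 2.38, 2.62 and 2.08, but microglia held fewer UMIs of each per 5XFAD nucleus than any other class, so these values were at background. Lypd1 was at 2.53 (1.46 to 4.72), with 1.68 in the female and 1.16 in the male mice and 1.09 times the UMIs per nucleus of the lowest class. On the lower side, Tac1 was at 0.104 (0.061 to 0.169) and Penk at 0.405 (0.280 to 0.585), both neuropeptide precursors made by neurons, at 1.48 and 1.34 times the lowest class level in the 5XFAD library. The cadherin Fat3 was at 0.407, the adhesion genes Ctnna3 and Lrrtm3 at 0.526 and 0.497, and the cell cycle kinase Cdk6 at 0.522. Fam102b, Ivns1abp and Zfand3 were at 0.567, 0.565 and 0.573. The ribosomal protein gene Rps29 was at 0.621 (0.555 to 0.695), with 1.33 times the lowest class level.

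**Figure D2:**
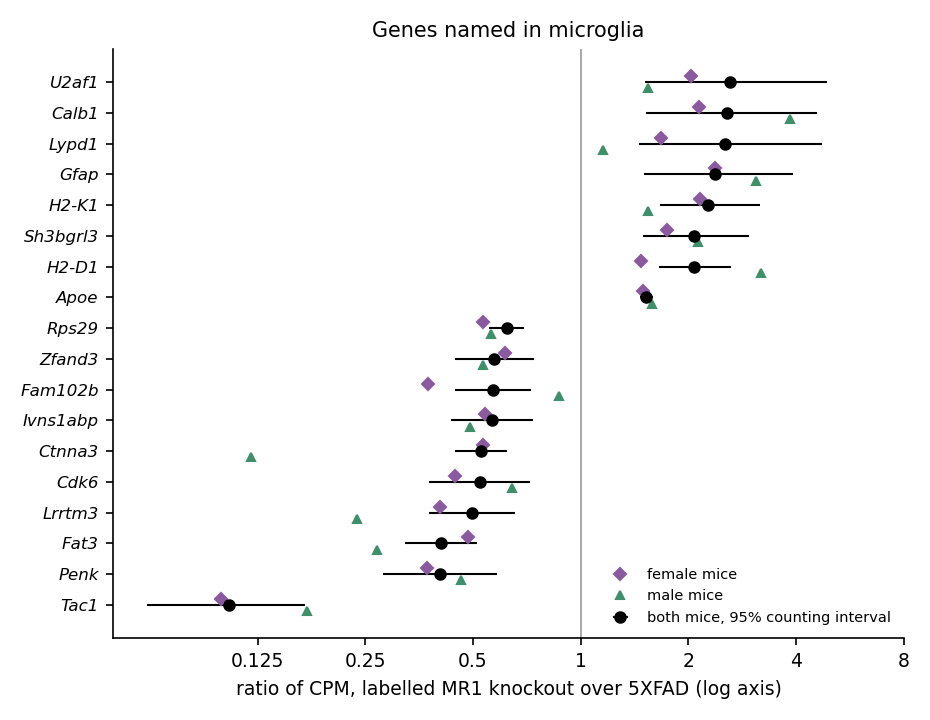
Ratio of CPM in microglia, library labelled MR1 knockout over 5XFAD, on a log axis, for 18 genes of the fixed rule; bars are 95% counting intervals and coloured points are the female and the male mice. H2-K1 at 2.28 and H2-D1 at 2.08 lie above 1 in both pairs of mice, and Tac1 at 0.104 lies below, since the rule asked for the same direction in both.

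Antigen presentation and interferon genes were also higher over all nuclei of the library labelled MR1 knockout. All 30 interferon response genes were higher, with a median log2 ratio of 0.83 (percentile 100) that was 0.82 in the female and 0.79 in the male mice. Oasl2, an oligoadenylate synthetase-like gene, was at 3.40 (2.54 to 4.61), the helicase Ddx60 at 3.05 (2.34 to 4.03), the ISG15 protease Usp18 at 2.98 (2.02 to 4.51) and the membrane tether Bst2 at 2.17 (1.92 to 2.46). All 19 MHC class I and peptide loading genes were higher (0.66, percentile 100), with H2-Q7 at 4.29 (2.92 to 6.47) and the immunoproteasome subunit Psmb8 at 1.84 (1.47 to 2.30), as were all 7 MHC class II genes (0.88, percentile 100), with H2-Aa at 1.85. All 16 complement genes were higher (0.42, percentile 99.6), with C1qa at 1.43 (1.38 to 1.48). Of the cytokine and NF-kB genes 18 of 23 were higher (0.36, percentile 96.6), led by the chemokine Cxcl10 at 4.97 (3.09 to 8.37), and Nfkb2 was at 0.714 (0.653 to 0.780). These values include the unnamed clusters, whose shares differed between the mice, and rest on a median gene at a log2 ratio of 0.13 over all nuclei, and microglia, whose markers were also higher, were a larger share of this library.

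T cell genes were close to the counting floor. Of 18 measured MAIT and T lymphocyte genes, 15 were higher over all nuclei, with a median log2 ratio of 0.31 (percentile 83.6). The T cell receptor complex gene Cd3g had 26 and 49 UMIs (1.89, 1.15 to 3.17) and the cytotoxic granule gene Nkg7 11 and 27 (2.46, 1.18 to 5.51). The coreceptor Cd4 had 46 and 16 UMIs (0.349, 0.185 to 0.629), and the receptor constant region Trbc2 81 and 43 (0.533, 0.359 to 0.781). No cluster carried the markers of T lymphocytes, so MAIT cells could not be looked at as cells.

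Apoe, Clu, Cst3, Sparc and Pla2g7 were the 5 highest genes of the fixed rule in astrocytes. Apoe was at 2.19 (2.11 to 2.28; 4212 and 8247 UMIs), Clu (clusterin) at 2.08 (1.88 to 2.29), the protease inhibitor Cst3 at 1.73 (1.64 to 1.81), the matrix glycoprotein Sparc at 2.65 (1.74 to 4.11) and the phospholipase Pla2g7 at 1.95 (1.66 to 2.28). Each was above 1 in both the female and the male mice, as the rule required. Disease-associated astrocyte genes were higher for 26 of 28 members, with a median log2 ratio of 0.72 (percentile 100; 0.56 in the female and 0.76 in the male mice). Plaque-induced genes were higher for 32 of 40 (0.56, percentile 100), MHC class I genes for 6 of 6 (0.86, percentile 100) and complement genes for 5 of 5 (0.19, percentile 85.8), with C4b at 1.90 (1.36 to 2.67). Interferon response genes were split, 4 higher and 4 lower (0.11, percentile 65.1; 0.76 when thinned, -0.08 in the female and 1.25 in the male mice), although their summed UMIs had a ratio of 1.38 (1.15 to 1.67), and of 2 cytokine and NF-kB genes 1 was higher (0.22, percentile 78.1). Homeostatic astrocyte genes were split, 12 higher and 10 lower (0.10, percentile 90.2; -0.05 when thinned), with the gap junction gene Gja1 at 1.57 (1.34 to 1.85), Luzp2 at 0.550 (0.506 to 0.596) and Gpc5 at 0.714 (0.679 to 0.751). Cholesterol biosynthesis genes were higher for 11 of 15 (0.26, percentile 94.6; -0.11 in the female mice). The lowest named genes were Pde10a at 0.292 (0.190 to 0.437), Rbms3 at 0.380, Eda at 0.395 and Phactr1 at 0.436. In the 5XFAD library these genes had 3.69, 12.2, 35.6 and 3.58 times the UMIs per nucleus of the class with the fewest. Pde10a was lower in 3 classes with a counting interval beyond 1.41-fold. Whether RNA from other cells added to these values was not tested. Phactr1 was at 0.902 in the female and 0.758 in the male mice, so nuclei assigned to neither mouse carried its value, and Luzp2 was at 0.825 and 0.476.

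Oligodendrocytes of the library labelled MR1 knockout also had higher MHC class I RNA, with little difference in myelin genes. All 8 measured MHC class I genes were higher (median log2 ratio 0.70, percentile 100), with H2-K1 at 2.38 (1.53 to 3.77), H2-D1 at 2.05 (1.58 to 2.68) and B2m at 1.65 (1.36 to 1.99). The median was 0.55 in the female and 0.22 in the male mice, with 5 members higher and 2 lower in both. Nuclei assigned to neither mouse thus carried part of the value. Disease-associated oligodendrocyte genes were higher for 14 of 18 (0.36, percentile 99.9), with C4b at 1.64 (1.40 to 1.94) and the glucocorticoid-induced kinase Sgk1 at 2.34 (1.58 to 3.50). Interferon response genes were higher for 7 of 9 (0.72, percentile 99.9), with Bst2 at 3.18 (1.78 to 5.94), complement genes for 6 of 6 (0.28, percentile 96.4; -0.15 with at least 1000 genes per nucleus) and plaque-induced genes for 40 of 45 (0.28, percentile 99.9). Myelin genes were higher for 13 of 19 (0.09, percentile 83.3), with Opalin at 0.867 (0.754 to 0.997), and cholesterol biosynthesis genes for 15 of 18 (0.25, percentile 93.9). Lypd1, Jpt1, Rasl10a and Enc1 were the other higher genes, at 2.55, 2.62, 2.64 and 2.05. Tac1 was at 0.122 (0.078 to 0.182), Penk at 0.387, the troponin gene Tnni1 at 0.155, the Hippo pathway scaffold Sav1 at 0.239 and Pbx3 at 0.368 (0.901 in the female and 0.453 in the male mice). Tac1, Penk, Lypd1, Jpt1, Rasl10a and Enc1 had at most 1.34 times the UMIs per nucleus of the class with the fewest, in the library where each was higher, so these values need not come from oligodendrocytes. With the female 5XFAD mouse set against the male mouse of the other library, the medians were -0.01 for MHC class I and -0.05 for disease-associated oligodendrocyte genes. In oligodendrocyte precursors the proteasome gene Psmc5 was at 2.97 (1.84 to 4.98), Uchl1 at 2.20, Map1lc3a at 2.30, Sncb at 2.5 and Myl12b at 2.23; these 5 had 1.05 to 1.4 times the UMIs per nucleus of the class with the fewest, so they were close to background. Their lower genes were Gm29514 at 0.474, Gm15584 at 0.498, the potassium channel Kcnt2 at 0.520, Rsrc1 at 0.536 and Egfem1 at 0.628.

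**Figure D3:**
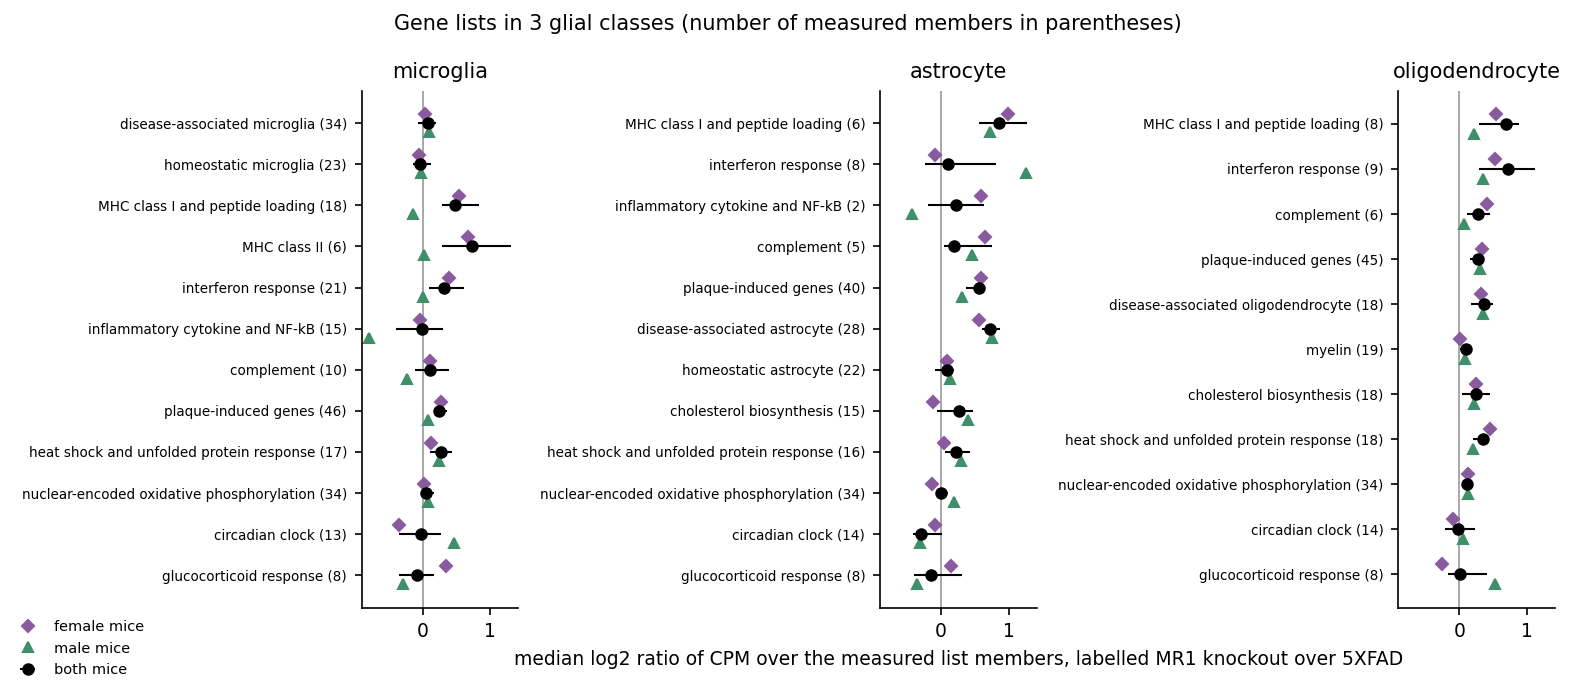
Median log2 ratio of CPM over the measured members of each gene list in microglia, astrocytes and oligodendrocytes, library labelled MR1 knockout over 5XFAD; black points and bars are both mice with a 95% interval, and coloured points are the female and the male mice. Disease-associated astrocyte genes sit at 0.72, and disease-associated microglia genes at 0.08.

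Genes of lysosomes, axonal transport and the neurite proteins that build up in dystrophic neurites had slightly higher CPM in every neuron class examined. All UMIs per nucleus had ratios of 0.576 in dentate granule, 0.668 in CA1, 0.702 in CA2/CA3 and 0.79 in inhibitory neurons. The higher share of the list could therefore come from fewer other UMIs, which was not tested. In dentate granule neurons 39 of 40 were higher, with a median log2 ratio of 0.36 (percentile 100) against a median gene at 0.14. The ubiquitin hydrolase Uchl1 was at 2.01 (1.85 to 2.18), the neurofilament Nefl at 1.73 (1.53 to 1.96), the tubulin-binding Stmn2 at 1.67 (1.52 to 1.83) and polyubiquitin Ubb at 1.54 (1.47 to 1.61). In CA1 pyramidal neurons 36 of 41 were higher (0.22, percentile 100; median gene 0.10), with Nefm at 1.55 (1.23 to 1.95) and Uchl1 at 1.51 (1.36 to 1.67). In CA2/CA3 pyramidal neurons 36 of 41 were higher (0.15, percentile 99.7; median gene 0.09), with the lysosomal membrane protein Tmem106b at 1.46 (1.24 to 1.73) and Ctsd at 1.30 (1.16 to 1.46). In inhibitory neurons 37 of 41 were higher (0.17, percentile 100; median gene 0.09), with the autophagy receptor Sqstm1 at 1.36 (1.18 to 1.56). TMM scaling shifted log2 ratios by 0.13 over all nuclei and by 0.15 in subicular or cortical neurons. In dentate granule, CA1, CA2/CA3 and inhibitory neurons it shifted them by 0.11, 0.12, 0.09 and 0.08. It left the list medians of these classes, in the same order, at 0.26, 0.09, 0.05 and 0.09. Most dentate granule nuclei were in cluster 2 in the 5XFAD library (1265, against 213 in cluster 0) and in cluster 0 in the other (3019, against 1113), and the list's median was 0.16 in either cluster alone. The percentile of 100 in dentate granule neurons belongs to clusters 0 and 2 together.

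Stress response genes had higher CPM in dentate granule and CA1 neurons, and activity-regulated genes went in different directions by class. All UMIs per nucleus had ratios of 0.576 in dentate granule and 0.668 in CA1 neurons. The higher share of stress response genes could therefore come from fewer other UMIs, which was not tested. Heat shock and unfolded protein response genes were higher for all 20 members in dentate granule neurons of clusters 0 and 2 (median log2 ratio 0.66, percentile 100), with the splicing-activated factor Xbp1 at 1.97 (1.64 to 2.38) and the chaperone Hsph1 at 1.92 (1.66 to 2.23). They were higher for 20 of 21 members in CA1 (0.34, percentile 100), 12 of 16 in astrocytes (0.22, percentile 96.7; -0.03 with the automatic doublet threshold), 13 of 18 in oligodendrocytes (0.35, percentile 99.7), 14 of 17 in microglia (0.27, percentile 99.2; -0.09 with at least 1000 genes per nucleus) and 23 of 25 over all nuclei (0.39, percentile 100). Immediate-early and activity-regulated genes were lower for 21 of 27 members in CA2/CA3 neurons (-0.23, percentile 0; -0.32 in the female and -0.38 in the male mice), with Egr1 at 0.484 (0.332 to 0.695), Npas4 at 0.461 (0.261 to 0.790) and the neurotrophin Bdnf at 0.633 (0.547 to 0.732), while Jun was at 1.69 (1.34 to 2.15). They were higher for 21 of 26 in CA1 (0.33, percentile 100; 0.05 in the female and 0.20 in the male mice), for 16 of 26 in dentate granule neurons of clusters 0 and 2 (0.18, percentile 67.4; -0.06 in the male mice and -0.37 in cluster 0 alone) and for 14 of 26 in inhibitory neurons (0.11, percentile 61.9; -0.05 in the male mice). Bdnf was at 2.09 (1.86 to 2.36) in dentate granule neurons and 1.87 (1.25 to 2.85) in inhibitory neurons.

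Receptor genes of fast synapses differed by class. Glutamate receptor and postsynaptic genes were lower for 22 of 30 members in dentate granule neurons of clusters 0 and 2 (median log2 ratio -0.08, percentile 5.97, against a median gene at 0.14; 0.09 in cluster 0 alone), 16 of them with an interval below 1, with the AMPA receptor subunits Gria1 at 0.706 (0.688 to 0.724) and Gria2 at 0.736 (0.720 to 0.753), and the postsynaptic calmodulin-binding protein Nrgn at 1.67 (1.58 to 1.75). In CA1 17 of 30 were higher (0.01, percentile 46.9; -0.11 under TMM scaling and -0.02 when thinned), with the TARP gene Cacng2 at 0.522 (0.399 to 0.676). In CA2/CA3 16 of 30 were higher (0.01, percentile 37.1; -0.09 under TMM scaling), with Grin2b at 0.882 (0.863 to 0.902). GABA synthesis and receptor genes were higher for 15 of 20 in inhibitory neurons (0.14, percentile 99.4), with the synthesis enzymes Gad1 at 1.29 (1.2 to 1.39) and Gad2 at 1.33 (1.24 to 1.42) and the vesicular transporter Slc32a1 at 1.41 (1.27 to 1.57). In dentate granule neurons 10 of 20 were higher (-0.03, percentile 12.4; 0.13 with the lowest class level removed), with Gabrg3 at 0.482 (0.434 to 0.535), and in CA1 12 of 20 (0.07, percentile 68.7; -0.06 under TMM scaling and -0.06 when thinned).

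Some genes differed several-fold in dentate granule neurons. The collagen chain Col6a1 (ENSMUSG00000001119, chromosome 10, 76708792 to 76726168) had 11 and 630 UMIs, a ratio of 35.6 (19.7 to 71.6). The semaphorin Sema3e was at 6.44 (5.08 to 8.26), the overlapping antisense gene Gm4128 at 16.8 (7.54 to 46.4), the cadherin Cdh7 at 10.0 (5.85 to 18.6) and the matrix protein Fbln2 at 8.70 (5.64 to 14.1). Their lower genes were the Wnt ligand Wnt9a at 0.142 (0.082 to 0.236), Kitl, the ligand of the Kit receptor, at 0.185, Onecut1 at 0.226 and Tspan18 at 0.252. In the female and male mice Cdh7 was at 14.5 and 4.28 (0.659 to 180.3), and Fbln2 at 14.3 and 1.43 (0.304 to 13.4). Kitl was at 0.0808 and 0.366, and Tspan18 at 0.0779 and 0.549. These ratios set clusters 0 and 2 in different proportions against each other. The strand that the tags came from was not stated in the sources used here, so counts of antisense genes such as Gm4128 are uncertain.

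In CA1 pyramidal neurons the cell cycle arrest gene Rprm was at 3.46 (2.28 to 5.37), the adrenergic receptor Adra2c at 3.27 (2.21 to 4.93), the chemokine-binding Ackr1 at 2.96 (1.98 to 4.52) and the glypican Gpc5 at 1.98 (1.90 to 2.06). Sav1 was at 0.290 (0.203 to 0.405), the neuropeptide precursor Cartpt at 0.347, 4930447N08Rik at 0.349, the keratin Krt12 at 0.462 and A730090N16Rik at 0.499. In CA2/CA3 neurons the collagen Col12a1 was at 3.95 (2.93 to 5.41), calretinin (Calb2) at 2.90 (1.90 to 4.55), Lypd1 at 2.23, Cd226 at 2.10 and Adamtsl1 at 1.94, while Sav1 was at 0.312 (0.245 to 0.394), Gm15997 at 0.354, Shisa4 at 0.496 and Rps29 at 0.605. Lypd1 in this class was at 1.42 (1.07 to 1.88) in the female and 11.4 (5.39 to 28.9) in the male mice. In inhibitory neurons the neuropeptide Y receptor Npy2r was at 3.78 (2.59 to 5.68), Oser1 at 3.52, Rprm at 3.13, Lypd1 at 2.69 and the protocadherin Pcdh8 at 2.49, while Aldh1l2 was at 0.265, Sav1 at 0.327, 9630002D21Rik at 0.332, 9330158H04Rik at 0.364 and the guidance ligand Slit2 at 0.435. Of these, 9630002D21Rik was at 0.670 (0.408 to 1.09) in the female and 0.117 in the male mice. In subicular or cortical excitatory neurons Gm49171 was at 6.68 (4.58 to 9.86), Lypd6b at 3.58, Nhs at 2.79, Gm10848 at 2.75 and the imprinted gene Nnat at 2.44, while Trabd2b was at 0.0499 (0.0102 to 0.148; 226 and 3 UMIs), Cpa6 at 0.182, Zfp804b at 0.185 and the netrin receptor Dcc at 0.223. Lypd6b was at 5.02 in the female and 1.18 in the male mice, Nnat at 2.63 and 1.21, and Zfp804b at 0.126 and 0.689. This class joined clusters 17 and 24, which held 173 and 239 nuclei of the female 5XFAD mouse against 135 and 19 of the other female, and 183 and 8 of the male 5XFAD mouse against 19 and 29 of the other male, so its ratios also set these clusters in different proportions against each other. Rprm and Cartpt in CA1, Calb2 and Rps29 in CA2/CA3, and Rprm and Lypd1 in inhibitory neurons had 1.1 to 1.49 times the UMIs per nucleus of the class with the fewest, in the library where each was higher, so these values need not come from the class.

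A non-coding transcript had almost no UMIs in the library labelled MR1 knockout in 3 neuron classes. Gm17167 (ENSMUSG00000091542, chromosome 4, 42206998 to 42235313) had 200 and 3 UMIs in dentate granule neurons (ratio 0.00932, 0.00191 to 0.0276) and 104 and 1 in CA2/CA3 neurons (0.00950, 0.000238 to 0.0541). In subicular or cortical excitatory neurons it had 127 and 0 UMIs, so it was at least 11.3-fold lower against a floor of 3 counts over the library, and the interval of its ratio reached 0.111. In these classes it was lower in the female and in the male mice, as the rule for named genes required.

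The fixed rule also named genes that lay on the same side of 1 in all 9 classes. The thyroid hormone carrier Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), made in bulk by the choroid plexus, was at 5.48 (5.36 to 5.59) over all nuclei and between 4.53 and 6.60 in the classes. It had 0.788 to 0.983 UMIs per nucleus in the classes of the 5XFAD library and 3.02 to 3.34 in the other. Tac1, abundant in striatal neurons, was at 0.263 (0.247 to 0.280) over all nuclei, with 0.4265 in the female and 0.165 in the male mice. In inhibitory neurons it was at 0.969 (0.816 to 1.15) in the female and 0.571 in the male mice. The value of Tac1 over all nuclei includes unnamed cluster 8, led by Rarb, Rgs9 and Drd2. That cluster held 1145 nuclei of the 5XFAD library, 699 of them assigned to the male mouse, and 5 of the other library. The dynein light chain Dynll1 was at 1.53, cyclophilin A (Ppia) at 1.51 and the 14-3-3 protein Ywhah at 1.55, although Ywhah was below 1 in the male mice in microglia (0.817) and oligodendrocyte precursors (0.923). Their UMIs per nucleus differed less. Over the classes of the 5XFAD library and of the other, they were 0.651 to 1.17 and 0.774 to 1.18 for Dynll1 (0.844 and 0.865 in dentate granule neurons of clusters 0 and 2), 1.51 to 1.95 and 1.66 to 1.93 for Ppia, and 0.349 to 0.872 and 0.408 to 0.953 for Ywhah. The higher CPM of these genes went with fewer other UMIs per nucleus.

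**Figure D4:**
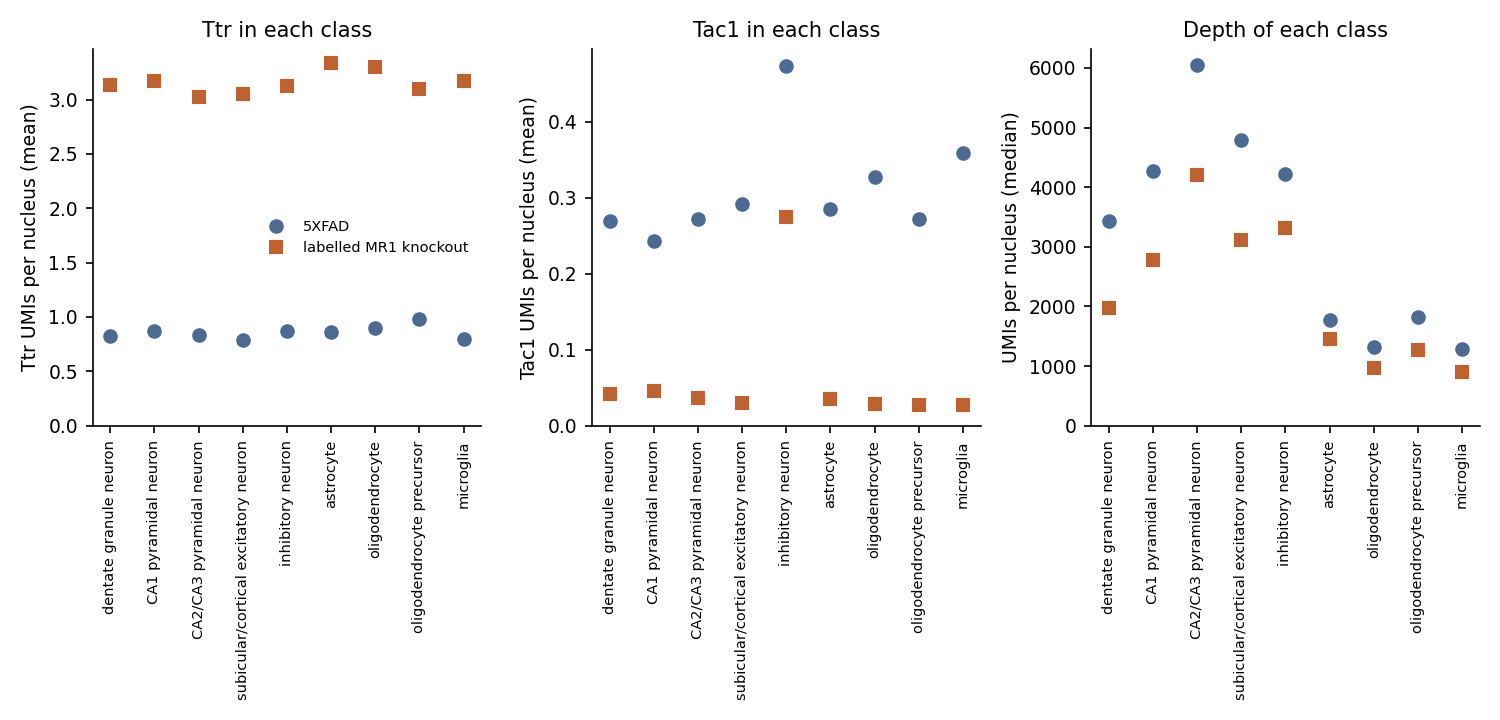
Mean UMIs per nucleus of Ttr and of Tac1, and the median of all UMIs per nucleus, in 9 classes of both libraries. Ttr lies between 0.788 and 0.983 UMIs per nucleus in every class of the 5XFAD library and between 3.02 and 3.34 in the other, while depth differs by class.

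Named genes were dense on the part of chromosome 1 that holds Mr1. The rule named 87 genes in the 9 classes, and 7 of them started within 20 Mb of Mr1 on chromosome 1, which is 4.02% of the 174 genes there that could have been named, against 0.804% of 10821 over the genome. The densest windows lay to the left of Mr1, with 4.21%, 6.19% and 4.97% at middles of 120, 130 and 140 Mb, and the window at 170 Mb held 0.971%. Of the 7, Ivns1abp (3.78 Mb away) was lower in microglia, Gm15584 (8.32 Mb), Gm29514 (8.71 Mb) and Kcnt2 (14.9 Mb) in oligodendrocyte precursors, Tnni1 (19.3 Mb) in oligodendrocytes and Shisa4 (19.8 Mb) in CA2/CA3 neurons. Ackr1 (18.2 Mb) was higher in CA1 neurons. Gm15584 and Gm29514 are annotated as antisense genes, and neighbouring genes are not independent.

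**Figure D5:**
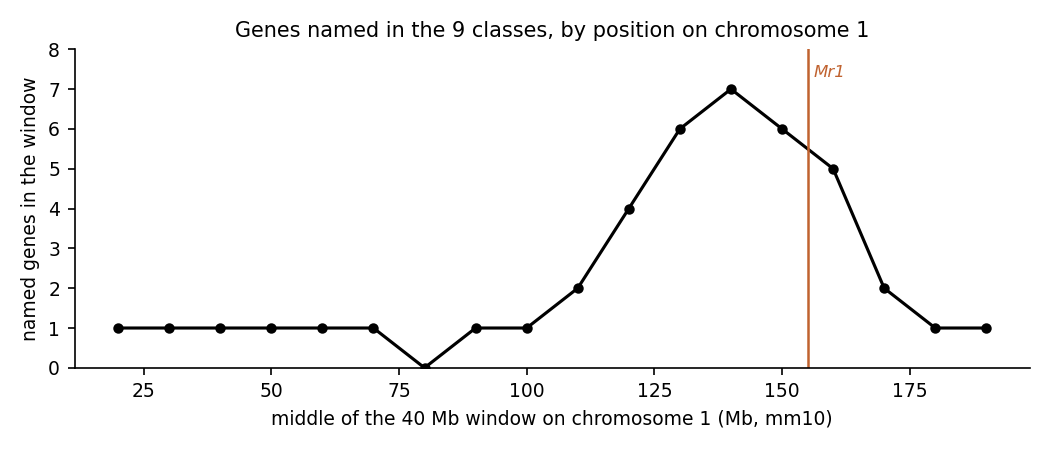
Number of named genes in windows of 40 Mb along chromosome 1, by the middle of the window in Mb (mm10); the vertical line is Mr1. Windows on the left of Mr1 and over it held up to 7 named genes, and windows below 100 Mb held at most 1.

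Mitochondrially encoded RNA was lower in the library labelled MR1 knockout, while nuclear genes of respiration differed by class. All 13 mitochondrially encoded genes were lower over all nuclei (median log2 ratio -0.49, percentile 0), with mt-Nd3 at 0.562 (0.549 to 0.575). The share of mitochondrial UMIs had medians of 1.81% and 1.2% per kept nucleus, and of 3.43% and 1.41% per barcode before filtering. The limit of 5% removed 35.8% and 8.92% of the barcodes, so these ratios describe only the nuclei under it. Nuclear-encoded oxidative phosphorylation genes were higher for 33 of 34 members in dentate granule neurons of clusters 0 and 2 (0.28, percentile 99.8), but the median was -0.18 with the lowest class level removed and -0.20 in cluster 0 alone. They were higher for 24 of 34 in CA1 (0.11, percentile 89.6; -0.04 in the male mice, -0.01 under TMM scaling and -0.37 with the lowest class level removed), 26 of 34 in oligodendrocytes (0.11, percentile 91.8; -0.83 with the lowest class level removed), 20 of 34 in microglia (0.05, percentile 88.4), 17 of 34 in astrocytes (-0.003, percentile 45.5; 0.59 with the lowest class level removed) and 25 of 34 over all nuclei (0.08, percentile 80.5; -0.05 under TMM scaling and -0.23 with no mitochondrial limit). Ribosomal protein genes were higher for 27 of 40 (0.07, percentile 96.2; -0.06 under TMM scaling and -0.65 with no mitochondrial limit), although Rps29 was at 0.692 (0.679 to 0.705) and Rpl41 at 0.771.

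Clock and glucocorticoid genes showed no common direction. Circadian clock genes had median log2 ratios of 0.17 in dentate granule neurons of clusters 0 and 2 (11 of 19 higher, percentile 63.9), 0.11 in CA1 (11 of 19, percentile 51.6; -0.02 under TMM scaling), -0.29 in astrocytes (5 of 14, percentile 1.16) and -0.06 over all nuclei (7 of 19, percentile 0.09; 0.17 in the female and -0.26 in the male mice). The medians were -0.02 in oligodendrocytes (6 of 14, percentile 21.1; 0.19 when thinned and 0.36 with the lowest class level removed) and -0.02 in microglia (6 of 13, percentile 40.9; 0.28 with the lowest class level removed). The clock medians in the female and male mice were -0.097 and 0.058 in oligodendrocytes, and -0.36 and 0.46 in microglia. In astrocytes the nuclear receptors Rora and Rorb were at 0.776 (0.699 to 0.861) and 0.741 (0.660 to 0.831), and over all nuclei Npas2 was at 0.603 (0.580 to 0.627). Glucocorticoid response genes had medians of 0.25 in CA1 (9 of 13, percentile 93.5), 0.11 in dentate granule neurons of clusters 0 and 2 (8 of 13, percentile 41.5; -0.04 when thinned), -0.15 in astrocytes (3 of 8, percentile 20.3; 0.08 when thinned) and -0.09 in microglia (3 of 8, percentile 22.9). They were 0.01 in oligodendrocytes (4 of 8, percentile 32.1; -0.06 under TMM scaling) and 0.09 over all nuclei (11 of 19, percentile 25.0; -0.04 under TMM scaling). Outside CA1 the glucocorticoid medians had opposite signs in the female and male mice. They were 0.071 and -0.094 in dentate granule neurons, 0.15 and -0.36 in astrocytes, and -0.26 and 0.53 in oligodendrocytes. In microglia they were 0.34 and -0.30, and over all nuclei 0.29 and -0.20. Adult neurogenesis genes were higher for 10 of 15 over all nuclei (0.22, percentile 89.2). Neurod1 was at 1.84 (1.60 to 2.11) and Sox11 at 1.40 (1.32 to 1.5), while Igfbpl1 was at 0.122 (0.0859 to 0.170). The share of dentate granule neurons, whose marker Prox1 is also in this list, had a ratio of 1.96. Values over all nuclei can thus come from the shares of classes, which was not tested. Igfbpl1 is among the leading genes of unnamed cluster 16, which held 637 nuclei of the 5XFAD library, 445 of them assigned to the male mouse and 1 to the female, and 6 of the other library.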

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

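Of the tests weighed here, all except the test of microglial RNA in other nuclei were chosen only after the result was seen.

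Ttr was higher, and Tac1 was lower, in every class of the library labelled MR1 knockout. Expression that changed within each class is argued against, since median depth differed at least 4.67-fold between classes of a library, while Ttr per nucleus differed at most 1.25-fold (1.06 to 1.46) and Tac1, outside inhibitory neurons, at most 2.92-fold at the top of its intervals. Free RNA, which reaches all nuclei alike, is a candidate explanation for Ttr. For Tac1 free RNA alone stays open, since its spread outside inhibitory neurons was 1.48-fold (1.15 to 1.89) in the 5XFAD library, an interval that spans the limit of 1.5. Dissection and the label as the origin of the free Ttr RNA cannot be told apart, since 48 choroid plexus nuclei were assigned to the male mouse labelled MR1 knockout (1.55% of its nuclei), 0 to the female of that label (at most 0.041%) and 2 to the male 5XFAD mouse, with 1 mouse of each sex per label.

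The interferon response list had a higher median in all 9 classes of the library labelled MR1 knockout, with log2 ratios of 0.11 to 0.87, although thinned medians ranged from -0.09 in inhibitory neurons and 0.06 in subicular or cortical neurons to 1.31 in oligodendrocyte precursors. Over the 8 classes other than microglia, microglia markers had a ratio of 1.22 (1.19 to 1.24) and the list 1.5 (1.44 to 1.56). This argues against RNA from more microglia of unchanged content. Within microglia the list was at 1.22 (1.08 to 1.37) and the markers at 1.08 (1.05 to 1.12). Microglial RNA richer in interferon genes therefore stays open. Fewer UMIs per nucleus stay open: the list's UMIs per nucleus had a median ratio of 1.10 (0.891 to 1.15 over the classes), all UMIs 0.702, so the list's higher share could come from fewer other UMIs. Free RNA of other kinds and an effect of the label on interferon genes stay open, as untested.

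Named genes were dense on the part of chromosome 1 that holds Mr1, and 20 genes, Gm17167 among them, were shifted the same way in at least 3 classes. Passenger DNA inherited with the Mr1 allele may account for the first, since 7 of 87 named genes lay within 20 Mb of Mr1, against a mean of 1.86 and a 95th percentile of 4 in 10000 draws, and none of 226 windows of 40 Mb that did not overlap this one held as many; 26 draws did. Its extent stays open, since the densest window lay to one side of Mr1, with 6.19% at 130 Mb against 4.02% on Mr1. As the cause of the 20 genes as a set it is argued against, since 18 lay on other chromosomes and the share on chromosome 1 was at most 31.7% by its exact interval, but it stays open for Lypd1, 29.3 Mb from Mr1. Lypd1 is also among the leading genes of unnamed cluster 18, which held 9 nuclei of the 5XFAD library and 603 of the other. Free RNA thus stays open for Lypd1 too, as untested. Free RNA is argued against for Gm17167, which differed 36.6-fold (14.0 to 136.5) per nucleus between classes of the 5XFAD library, while other strain differences and the label stay open, as untested.

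Several shares lay on opposite sides of 1 in the female and in the male mice, and these differences were not tested. The share of CA1 pyramidal neurons had a ratio of 0.312 in the female and 1.68 in the male mice. The share of CA2/CA3 pyramidal neurons had ratios of 0.453 and 3.10. The share of inhibitory neurons had ratios of 0.826 and 1.75. The share of unnamed clusters had ratios of 2.09 and 0.286.

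Some unnamed clusters, which entered the comparisons over all nuclei but not those of a class, belonged almost wholly to 1 or 2 of the 4 mice. Their brain region was not determined here, so the tissue taken could differ between the mice, also for the glial classes. Cluster 4, led by Smoc1 and Otof, was 19.7% of the nuclei of the female mouse labelled MR1 knockout. Cluster 8, led by Rarb, Rgs9 and Drd2, was 20.3% of the nuclei of the male 5XFAD mouse. Cluster 9, led by Rmst and Slc17a6, was 8.27% of the nuclei of the female mouse labelled MR1 knockout and 3.97% of those of the male 5XFAD mouse. Cluster 16, led by Ano1 and Prdm16, was 12.9% of the nuclei of the male 5XFAD mouse. Cluster 18, led by Gm11639, Rmst and Npsr1, was 6.39% of the nuclei of the female mouse labelled MR1 knockout. Cluster 19, led by Pdzrn3, Bmpr1b and Rorb, was 11.5% of the nuclei of the male 5XFAD mouse. In the mice not named, each of these clusters held under 1% of the nuclei.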

How the results depend on the processing

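The alternatives chosen only after the data were seen were no mitochondrial limit, the automatic doublet threshold, the female 5XFAD mouse against the male mouse of the other library, each dentate granule cluster alone, the lowest class level removed and, for shares, mixed clusters kept under their leading class. No paired analysis was possible because the groups share replicate number 1 but hold 1 library each, and no result comes from a test. Of 1381 values of 100 gene results under an alternative, 1099 stayed within their counting interval, 282 moved and 0 reversed. Of 1156 values of 73 list medians, 860 stayed, 268 moved and 28 reversed. Of 129 values of 9 shares, 69 stayed, 54 moved and 6 reversed. The rule for named genes asked for the same direction in the female and in the male mice, which excluded a reversal in either sex alone. The 0 reversals of genes are therefore not comparable with those of lists and shares, which were not selected this way. Oligodendrocyte precursors formed no class at 0.5 times the resolution. Counts limit genes with few UMIs, and 1 library per group limits all results. For the values that follow, given as ratios for shares and median log2 ratios for lists, the cause was not tested.

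Under TMM scaling the dystrophic neurite list was at 0.26 in dentate granule, 0.092 in CA1, 0.052 in CA2/CA3 and 0.089 in inhibitory neurons, oxidative phosphorylation at -0.013 in CA1 and -0.053 in all nuclei, ribosomal protein at -0.061 and the clock in CA1 at -0.015. With at least 1000 genes the shares were 1.71 for dentate granule neurons, 0.612 for astrocytes, 0.227 for oligodendrocytes and 0.746 for microglia, and the medians -0.16 for homeostatic microglia, -0.15 for oligodendrocyte complement, -0.087 for microglial heat shock and -0.011 for oligodendrocyte oxidative phosphorylation. With at least 200 genes the oligodendrocyte share was 0.926. With the automatic doublet threshold the shares were 1.75 for dentate granule neurons, 0.730 for CA1 and 0.714 for oligodendrocytes, and the medians -0.17 for homeostatic microglia, 0.46 for disease-associated astrocytes and -0.025 for astrocyte heat shock. By the highest marker score the shares were 1.62 for dentate granule neurons, 0.698 for CA1, 0.713 for oligodendrocytes and 1.82 for microglia. The microglia share was 1.61 at 0.5 times the resolution and 1.55 with mixed clusters kept. Among glial and vascular nuclei the shares were 0.676 for oligodendrocytes and 1.86 for microglia.

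In dentate granule cluster 0 alone the activity-regulated list was at -0.37, dystrophic neurite at 0.16, glutamate receptor at 0.088 and oxidative phosphorylation at -0.20, and in cluster 2 alone dystrophic neurite was at 0.16. With the lowest class level removed, disease-associated astrocyte was at 0.92, disease-associated oligodendrocyte at 0.56, dystrophic neurite at 0.19 in dentate granule and 0.078 in CA2/CA3 neurons, and oxidative phosphorylation at -0.18 in dentate granule neurons, -0.37 in CA1 and -0.83 in oligodendrocytes. When thinned, disease-associated astrocyte was at 0.57.

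With the female 5XFAD mouse against the male mouse of the other library, the shares were 1.12 for dentate granule neurons, 1.29 for CA1, 0.906 for oligodendrocytes, 0.558 for oligodendrocyte precursors and 0.784 for microglia. The medians were 0.30 for disease-associated and -0.17 for homeostatic microglia, -0.007 for oligodendrocyte MHC class I, 0.38 for disease-associated astrocytes, -0.054 for disease-associated oligodendrocytes, -0.18 for activity-regulated in dentate granule neurons, 0.25, 0.15 and 0.094 for dystrophic neurite in dentate granule, CA1 and inhibitory neurons, -0.03 for oxidative phosphorylation in CA1, -0.065 for ribosomal protein and 0.071 for the clock in all nuclei. In the female mice the shares were 1.05 for dentate granule neurons, 0.312 for CA1, 0.826 for inhibitory neurons, 0.686 for oligodendrocytes and 1.72 for microglia, and the medians 0.56 for disease-associated astrocytes, 0.47 for dystrophic neurite in dentate granule neurons and 0.17 for the clock in all nuclei. In the male mice the shares were 6.64 for dentate granule neurons, 1.68 for CA1 and 0.584 for astrocytes, and the medians -0.14 for microglial MHC class I, -0.059 for activity-regulated in dentate granule neurons, 0.16, 0.10 and 0.075 for dystrophic neurite in dentate granule, CA1 and inhibitory neurons, and -0.04 for oxidative phosphorylation in CA1.

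With no mitochondrial limit the shares were 2.29 for dentate granule neurons, 0.945 for CA1, 0.905 for astrocytes, 0.620 for oligodendrocytes and 1.45 for microglia, and the medians 0.32 for disease-associated and 0.23 for homeostatic microglia, 0.97 for disease-associated astrocytes, 0.55 for disease-associated oligodendrocytes, 0.14 for dystrophic neurite in CA1, -0.04 and -0.23 for oxidative phosphorylation in CA1 and all nuclei, and -0.65 for ribosomal protein. Under 1% mitochondrial UMIs the shares were 2.35 for astrocytes, 7.78 for oligodendrocytes and 6.80 for microglia, and the medians 0.78 for disease-associated and 0.31 for homeostatic microglia, 0.94 for disease-associated astrocytes, 0.99 for disease-associated oligodendrocytes, 0.49, 0.31 and 0.29 for dystrophic neurite in dentate granule, CA1 and inhibitory neurons, and 0.005 for the clock in all nuclei.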

Other observations

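The comparison in this part was chosen only after the results were seen. A set of 20 genes was shifted the same way in at least 3 of the 9 classes, with a counting interval beyond 1.41-fold in each of them, 11 higher and 9 lower in the library labelled MR1 knockout. Lypd1 was higher in 6 classes, with ratios of 1.31 to 2.69 over the classes that held at least 100 UMIs of it, and the other ranges are over such classes too. Rprm, a cell cycle arrest gene, was higher in 5 classes (2.11 to 6.04), the secreted glycoprotein Olfm1 in 5 (1.30 to 1.68), the ubiquitin hydrolase Uchl1 in 4 (1.23 to 2.20) and Oser1, an oxidative stress-responsive gene, in 3 (2.48 to 3.52). Sav1, a scaffold of the Hippo pathway, was lower in 5 classes (0.239 to 0.450), and the neuropeptide precursor Cartpt in 4 (0.342 to 0.497). Rps29, lower in 3 classes (0.605 to 0.861), and Sav1 lie close to each other on chromosome 12, at 69157722 to 69159186 and 69965012 to 69987002 in mm10. The levels of Lypd1 in 3 of the classes that name it, of Rprm in CA1 and inhibitory neurons and of Cartpt in CA1 neurons were at most 1.38 times that of the class with the fewest UMIs per nucleus, so these values need not come from the class. The same holds for Rps29, at 1.49 times that level in CA2/CA3 neurons and 1.33 times in microglia of the 5XFAD library.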
